A study of Chlamydomonas reinhardtii with 2 samples.

How the data were processed

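The samples were poly-A selected RNA from cultured cells of the green alga Chlamydomonas reinhardtii, fragmented and read as single ends of 35 nt. Both titles name strain 2137 (culture collection number 1021) in Tris-acetate-phosphate medium with the revised trace element supplement, so both were placed in 1 group, with the replicate number from the title. The strain tag of the second sample reads 2138, in conflict with its own title, and the title was followed. No other medium is in the samples used here, so no comparison of media was made.

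The deposited values are raw read counts. Per the authors' deposited readme, reads from the Solexa pipeline were aligned with SOAP (version not given in the sources used here) to the unmasked version 3.1 assembly of the Chlamydomonas genome, which has 1266 scaffolds. Round 1 allowed up to 2 mismatches and no indels. Reads left over were trimmed base by base at either end, down to 21 nt, until they matched perfectly. The deposited table of each library holds the uniquely aligned reads only, as the start position of the alignment, its length in nt and the count of reads. Positions run along the scaffolds joined end to end. The tables carry no scaffold name, strand, gene or sequence, and whether the first base counts as 0 or 1 is not given, so positions are printed as deposited. Reads from near-identical gene copies and repeats do not align uniquely and are missing from the counts. A read trimmed by 1 or 2 bases to a perfect match would have had at most 2 mismatches and passed round 1, and the tables hold 0 reads of 34 nt and 590 of 33 nt.

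The gene annotation at hand is of assembly version 5.5, whose coordinates differ from those of the files, so no read could be assigned to a gene. The gene lists fixed before the data were examined (26 lists, such as copper, iron, zinc and manganese deficiency markers, ribosomal proteins and life-stage markers) therefore gave 0 matched genes and no result, and neither did the rule for named genes as far as it rests on gene names. Windows of 1 kb of global position took the place of genes, which departs from the planned design. By the same rule the 15 windows of highest level are described, and windows that differed between libraries would have been named had any passed the test.

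Counts per window were scaled to a total of 1000000 uniquely aligned reads (RPM). Replicate counts were compared with the chi-square expected from splitting each window's summed count at the ratio of library totals scaled by TMM (edgeR 4.0.16), over windows with a summed count of at least 10. The mean chi-square was set against 1000 simulated binomial splits (200 for single positions), and the p is the share of splits with a mean as high. Each window was also tested with a two-sided exact binomial test, Benjamini-Hochberg adjusted, at a threshold of 0.05. Dispersion was estimated with edgeR under an intercept-only design, and the coefficient of variation beyond counting error by the method of moments with a bootstrap over windows or positions. DESeq2 1.42.0 supplied median-of-ratios size factors as an alternative. Because the libraries differed by little more than sampling noise at the scale of windows they were counted as 1 sample and summed. Levels carry exact Poisson intervals and shares exact Clopper-Pearson intervals, both of 95% and covering counting error only, since reads without molecular identifiers are not independent molecules.

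Candidate exon edges were taken from trimmed alignments of up to 32 nt. A left edge is a position where trimmed alignments of at least 6 different lengths begin, and a right edge one where at least 6 lengths end. Control piles placed the far end on the wrong side (start minus length) or at double the length. A right and a left edge that were each other's nearest, 50 to 2000 nt apart, with mean depth between them under 20% of the depth in the 30 nt on each side taken separately, were called a candidate intron. The same edges settled which end of an alignment the position names: in the summed libraries 5517 left and 5349 right edges were found, against 926 and 944 control piles, so positions were read as the leftmost base of every alignment.

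The share of trimmed reads (all alignments under 35 nt) was computed per 1 kb window of at least 50 reads. Its median was taken per 200 kb bin with at least 10 such windows, and bins above the 90th percentile were joined into runs, passing over bins with too few windows. The longest run was compared with 100000 random orders of the bins. Runs were also chosen from windows of at least 50 and under 200 reads and then measured in windows of at least 200 reads, a test added after the runs were seen. The use and size of windows, and the edges, introns and bins with their settings, were chosen after seeing the files, while the scaling and the minimum count used to compare the libraries had been planned for genes.

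The binomial test was tested on simulated data made from the summed counts of the 44135 windows, with 200 windows changed. Of changed windows with at least 100 reads it called 4 of 11 at 1.5-fold, 15 of 17 at 2-fold and 14 of 14 at 4-fold. Over all depths it called 16 of 50 at 2-fold and 21 of 50 at 4-fold, with 3 false calls among 43935 unchanged windows. The intron search recovered 192 of 200 planted introns and made 0 other calls in trimmed reads moved at random. Every planted intron had trimmed reads of many lengths at both edges and deep flanks, so recovery at shallow edges was not measured. Moving reads at random breaks up shared ends, so the lack of other calls says little about chance piles. Control piles in the unmoved reads gave 30 pairs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and matplotlib 3.10.9 were used.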

Results

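Messenger RNA of Chlamydomonas reinhardtii, a single-celled green alga that grows on acetate in the light, was sequenced from cells of strain 2137 in Tris-acetate-phosphate medium carrying a trace element supplement revised from measurements of the cells' own mineral content. Cultures were kept at 23 °C in continuous light of about 50 to 90 µmol photons per square metre and second, and diluted 1 to 100 into fresh medium at mid to late log phase. The group held 2 samples, replicate 1 with 5380216 uniquely aligned reads and replicate 2 with 5787626. In sum 11167842 reads were available, so that 1 read equals 0.0895 RPM (reads scaled to a total of 1000000). For a window with no read, 0.269 RPM (3 reads) was taken as the upper bound of its level. That bound holds only where reads can align uniquely. The labels do not say whether the samples came from separate cultures, so any p-value between them measures only the spread between these samples, which may be technical. The series title concerns gains in biomass and growth rate under the revised supplement, but no second medium was analysed here, and the values below describe the transcriptome in this medium alone.

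The transcribed regions of the genome had close levels in both libraries. Across 44135 windows of 1 kb with at least 10 reads in sum, log2(RPM + 0.1) had a Pearson r of 0.957 and a Spearman rho of 0.916 (across windows, which are not independent replicates). In the 10413 windows with at least 100 reads the Pearson r was 0.992. No window with 20 or more reads in one library lacked reads in the other: the highest count facing 0 reads was 13 in replicate 1 and 14 in replicate 2. The 3 most abundant windows had 10490 and 10407 RPM, 10305 and 10280 RPM, and 8730 and 8748 RPM in replicates 1 and 2.

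The scatter that remained was close to that of counting. The mean chi-square per window was 1.006, within the 0.987 to 1.013 of the central 95% of simulated splits (simulated p = 0.206, 44135 windows). Under the two-sided exact binomial test 0 windows passed an adjusted p of 0.05, while 1779 windows (4.03%) had an unadjusted p under 0.05. The window with the lowest p, at 97219001 to 97220000, was singled out after its values were seen: it had 119 reads in replicate 1 and 208 in replicate 2, with an adjusted p of 0.598 from the exact binomial test. The edgeR estimate of the common biological coefficient of variation was 0.988%, which is the lowest value its search returns. The moment estimate was 0.408% (95% bootstrap interval 0.133 to 0.591). The departures from it were small. In the 558 windows with 3000 or more reads the mean chi-square was 1.17 (simulated p = 0.0050), at a coefficient of variation of 0.406%, and over 156743 single start positions it was 1.013 (simulated p = 0.0050, the smallest that 200 splits can give). At the scale of windows the libraries differed by little more than sampling noise, and they were counted as 1 sample from here on.

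**Figure D1:**
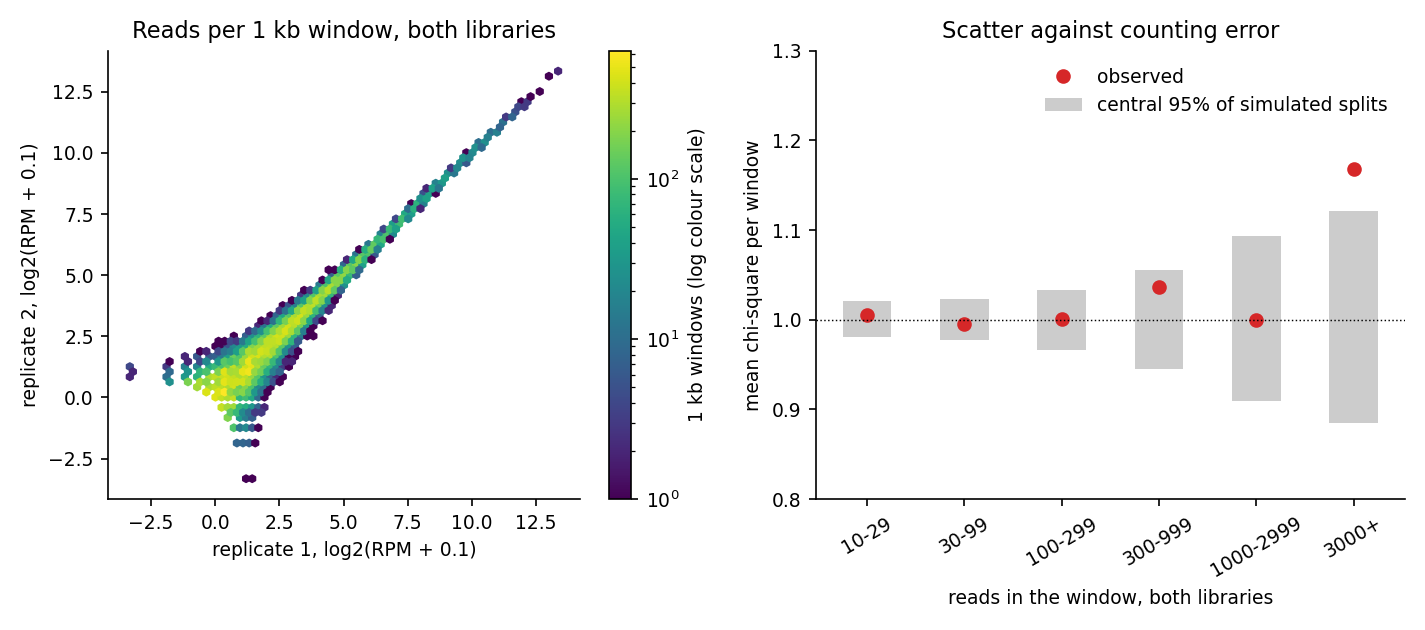
Left, RPM in each 1 kb window (log2 scale, 0.1 RPM added) in replicate 1 against replicate 2, coloured by the number of windows, for 44135 windows with at least 10 reads. Right, the mean chi-square per window by the number of reads in the window (points), with the central 95% of simulated binomial splits (grey bars): only the class of 3000 or more reads, at 1.17, lies outside its bar.

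Uniquely aligned reads covered a small part of the assembly at this depth, and a few regions supplied most of them. Reads lay on 24.6 Mb, or 21.9% of the 112.3 Mb spanned, and 83672 of 112306 windows (74.5%) held at least 1 read. The median window with reads had 11 of them (0.985 RPM), the 95th percentile was 282 reads (25.3 RPM) and the highest 116668 reads (10447 RPM). Only 407 windows, 0.362% of the assembly, held 50% of the reads. The 100 most abundant windows held 26.1% and the 1000 most abundant 63.1%. Each library alone also gave 407 such windows, whereas 5190 windows (4.62%) held 50% of the records when each position and length was counted once.

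Low-abundance regions were still being found at this depth. When reads were thinned to 50%, 76238 windows held a read in place of 83672, and 31354 in place of 44135 held at least 10. The remaining 28634 windows (25.5%) without a read cannot be called silent, since repeats and near-identical gene copies give no unique alignments and unsequenced stretches of the assembly give none either.

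**Figure D2:**
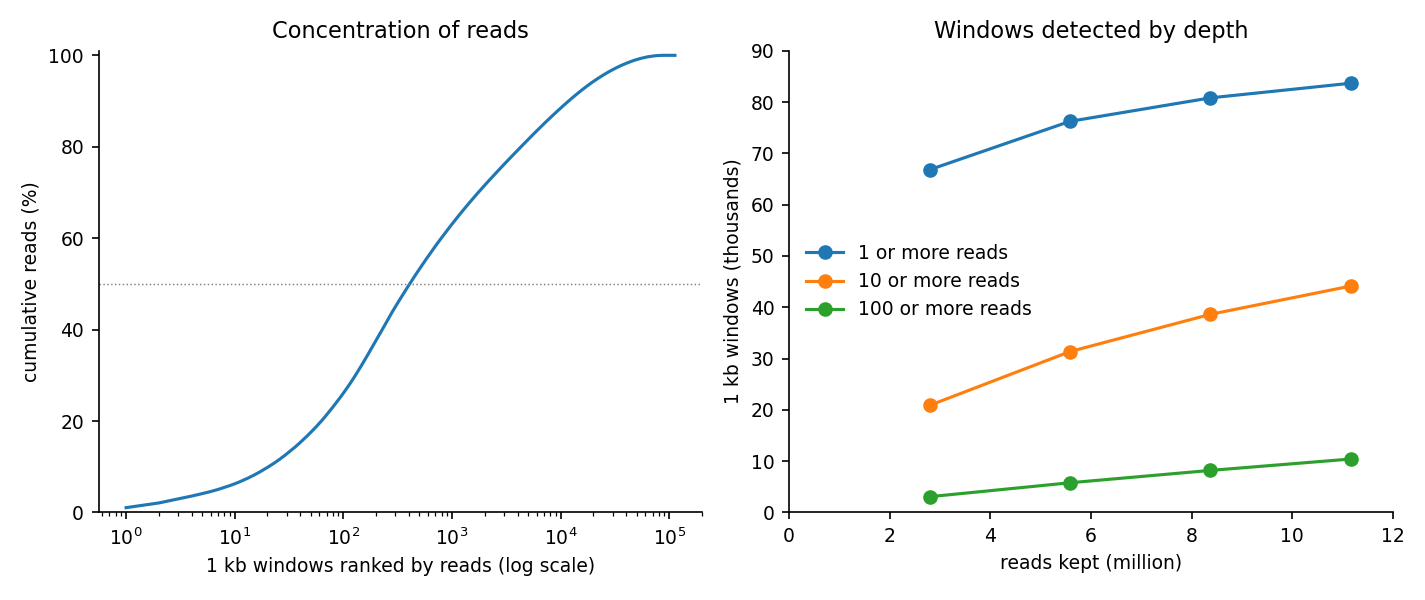
Left, cumulative percent of reads over 1 kb windows ranked by reads (log scale), with 50% reached at 407 windows. Right, number of windows (axis in units of 1000) with at least 1, 10 and 100 reads against the reads kept after thinning (axis in units of 1000000): at all reads these were 83672, 44135 and 10413.

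The 15 most abundant windows lay at 14 separate places of the assembly, with levels from 10447 RPM down to 3629 RPM. The first was at 106390001 to 106391000 on the global coordinate of assembly version 3.1, with 10447 RPM (95% Poisson interval 10387 to 10507), 1.04% of all reads. The window next to it, 106389001 to 106390000, ranked eighth with 4419 RPM (4381 to 4459). The second window, 108992001 to 108993000, had 10292 RPM (10233 to 10352), and its position 108992364 was the start of 5217 reads, the most of any position. The third, 73904001 to 73905000, had 8739 RPM (8685 to 8794). The fourth, 16023001 to 16024000, had 6291 RPM (6244 to 6337), and the fifth, 84899001 to 84900000, had 5338 RPM (5296 to 5381). Within the third window 38.7% of positions were the start of a read and the highest single position took 4.74% of its reads. In the tenth, 92903001 to 92904000, 99.6% of positions were. The ratio of replicate 2 to replicate 1 lay between 0.989 and 1.004 in these windows, and none differed (exact binomial test, adjusted p = 1 in each). The genes in these windows were not identified here.

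Candidate exon edges and introns were found from the trimmed alignments, which were 1043939 reads or 9.35% (9.33 to 9.36). A base where trimmed alignments of at least 6 lengths stopped or began was taken as an edge, and edges without a partner were left out. In all, 1413 candidate introns were found, with a median length of 207 nt (95% bootstrap interval 201 to 217) and an interquartile range of 144 to 327 nt. Of these 70.3% were 100 to 400 nt long. The same search on control piles gave 30 pairs, 2.12% of the number found. Without the depth limit it gave 84 pairs against 1654, or 5.08%. Control piles lie beyond the reads that make them, where depth can differ, so these shares are not rates of false calls. Both edges were seen with at least 3 lengths in each library separately for 1287 of the candidate introns (91.1%). They were called on the summed libraries, so this support is partly given by the call. Calls made in each library alone shared 661 with the same ends.

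Depth fell steeply across these edges, and little RNA was read inside the candidate introns. The median depth inside was 0.263% of that in the 30 nt on each side (interquartile range 0.109 to 0.583%), where the flanks had a median depth of 99.9 reads. A limit of 20% was part of the definition. Without it, 1654 pairs had a median of 0.339%. At 35 nt before an intron the median depth was 106% of that 36 to 70 nt into the exon, and at the last exon base 41.3%, where full-length alignments alone had a median of 8.40% and trimmed alignments one of 31.1% (separate medians over 1218 introns, which need not add up). Counts near these exon ends were thus lower than further into the exon. Between consecutive candidate introns up to 2000 nt apart lay 906 internal segments with a median of 132.5 nt (interquartile range 85 to 231 nt), which may still hold introns that were not found.

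Candidate introns of the most abundant regions illustrate this. In the first window a candidate intron of 146 nt at 106390049 to 106390194 had a mean depth of 6.29 inside against 2900 and 2902 in its flanks. There 1116 trimmed reads ended at its left side and 1088 began at its right. In the neighbouring window a candidate intron of 234 nt at 106389143 to 106389376 had 2.23 inside against 2912 and 2034. In the fifth window a candidate intron of 209 nt at 84899190 to 84899398 had 4.33 inside against 1629 and 1851. The fifteenth window, 35742001 to 35743000, held 2 candidate introns, of 236 nt at 35742022 to 35742257 and 279 nt at 35742392 to 35742670. They had 1.70 and 2.56 inside and flanks above 1000. In total 12 of the 15 most abundant windows touched a candidate intron. Those in the deepest windows with under 20 trimmed reads at an edge, such as the 180 nt at 73904456 to 73904635 in the third window with 16 and 17, are less certain, because chance piles are more frequent there. The number of candidate introns depended on depth: 798 were found in replicate 1 and 851 in replicate 2 alone, 661 of them with the same ends.

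**Figure D3:**
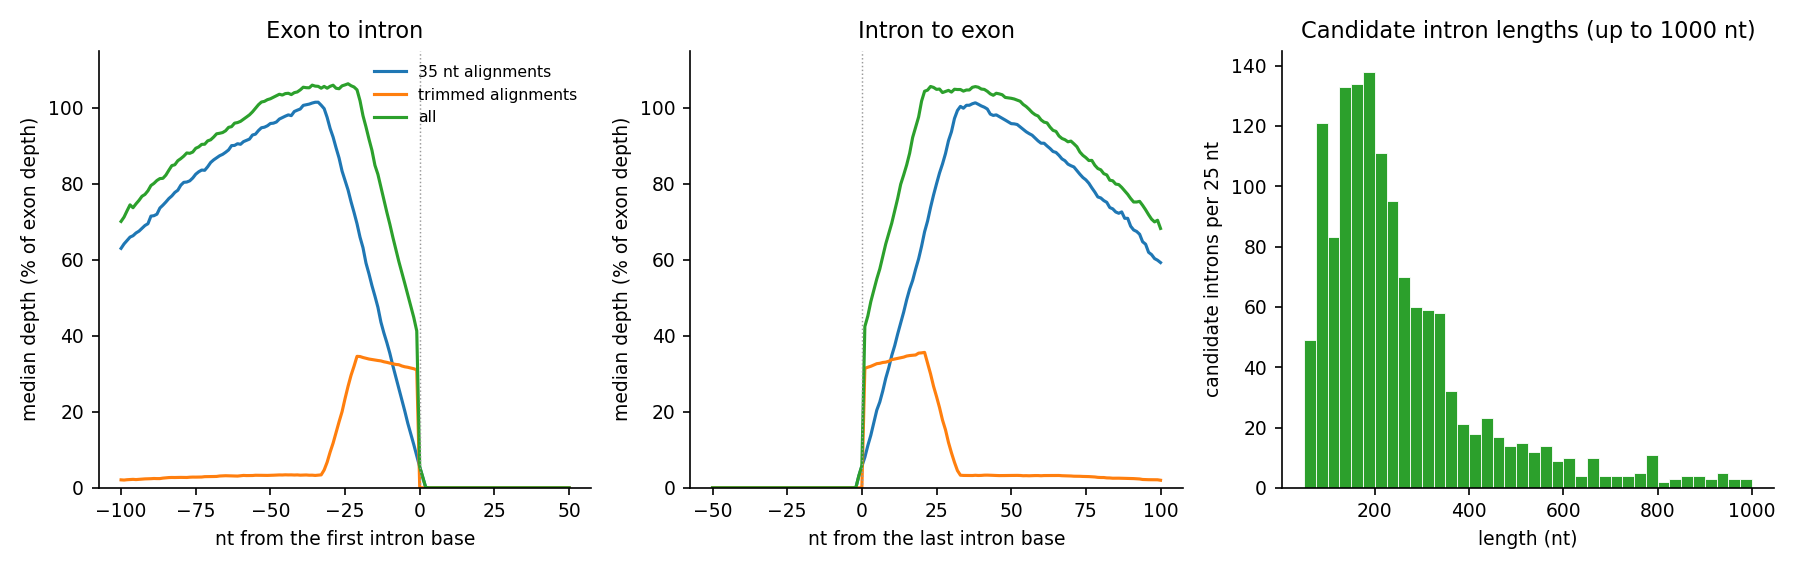
Left and middle, median depth (percent of the depth 36 to 70 nt into the exon) by distance in nt from the first and the last base of the candidate introns of at least 100 nt, for 35 nt alignments, trimmed alignments and all alignments, over 1218 and 1213 introns: all fall to 0 within 3 nt inside the intron. Right, number of candidate introns per 25 nt of length, up to 1000 nt, around the median of 207 nt.

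The share of trimmed reads differed slightly between the libraries and more strongly between parts of the genome. It was 9.23% (9.20 to 9.25) in replicate 1 and 9.46% (9.44 to 9.49) in replicate 2, a difference of 0.236 points (the intervals cover counting error only, and with 1 library on each side no test of this difference is given). Over 528 bins of 200 kb the median share per window had a median of 6.10%, an interquartile range of 5.35 to 7.15% and a maximum of 16.0%. Runs of 3 or more bins above the 90th percentile (8.26%), passing over bins with too few windows, occurred at 4 places. They were 34.2 to 35 Mb (median over windows 12.3%), 35.4 to 36 Mb (10.2%), 100.2 to 101.6 Mb (11.1%) and 105.8 to 106.4 Mb (12.5%). The runs at 34.2 to 35 Mb and 100.2 to 101.6 Mb hold bins that were passed over, so their high bins do not all adjoin. The run at 105.8 to 106.4 Mb holds the most abundant window. The longest run, of 4 bins at 100.2 to 101.6 Mb, was reached in 4.19% of random orders (permutation test, p = 0.0419). It rests on passing over bins, as the random orders also do. In bins of 100 kb the longest run was 6 bins at another place, 34.2 to 35.1 Mb (permutation p = 6.3e-04). With windows of at least 200 reads the longest run did not pass the test (2 bins at 0.8 to 1.4 Mb, permutation p = 0.951). Nor did it in replicate 2 alone (3 bins at 34.2 to 35 Mb, permutation p = 0.346) or in replicate 1 alone (2 bins at 34.2 to 34.6 Mb, permutation p = 0.993). Where runs tie in length, the first along the assembly is given. These alternatives therefore do not test the run at 100.2 to 101.6 Mb itself. The share pooled over all reads of a bin, not the median over windows that gave the runs, was also compared between the libraries. Across 552 bins it had a Pearson r of 0.970 (bins are not independent replicates). The mean chi-square of its difference per bin was 1.05 (bootstrap interval 0.918 to 1.18). These values do not test whether the runs repeat.

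**Figure D4:**
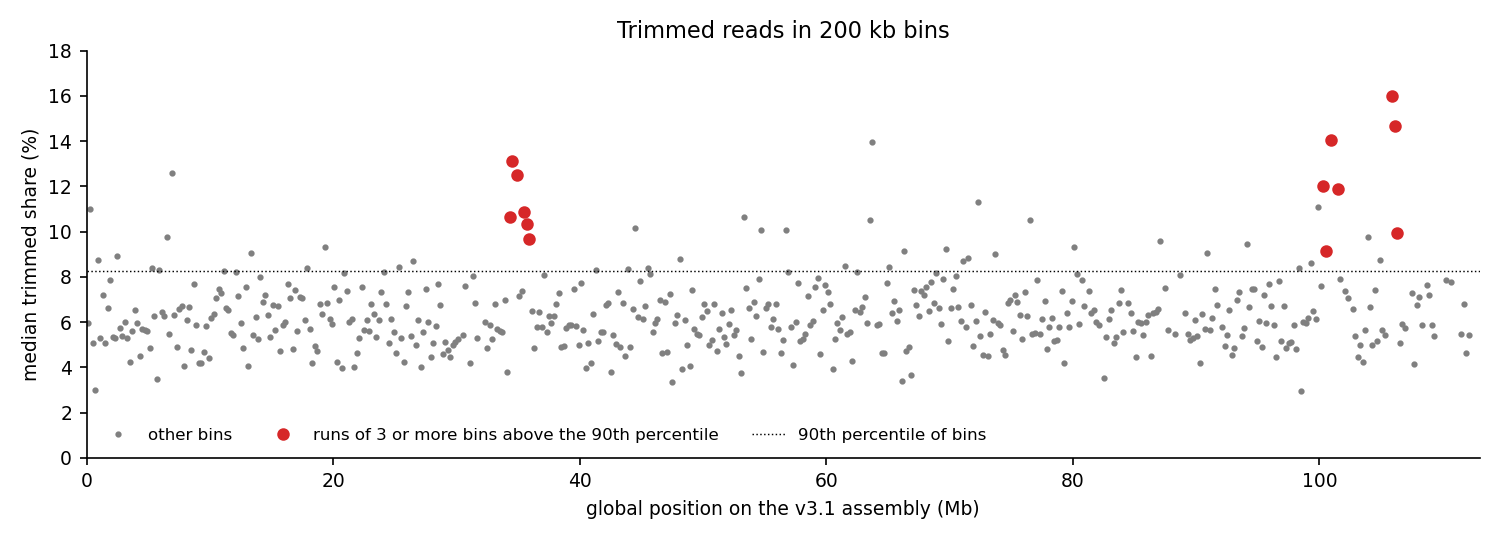
Median share of trimmed reads (percent) per 200 kb bin along the global position of assembly version 3.1 (Mb). Red points are the runs of 3 or more bins above the 90th percentile of 8.26% (dotted line), 4 in number, at 34.2 to 35, 35.4 to 36, 100.2 to 101.6 and 105.8 to 106.4 Mb, and grey points are the other bins, around a median of 6.10%.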

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

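The use of windows in place of genes, window sizes and single positions, the windows that hold 50% of the reads, introns and runs of bins, with the alternatives of these, were chosen after seeing the data; the alternatives in scaling, minimum count, added RPM and counting of positions were planned for the agreement of the libraries. The count of 0 differing windows held under all 5 alternatives. The mean chi-square stayed within simulated splits under 6 of its alternatives. For single start positions it was 1.013, past the threshold. With each position and length counted once it reversed to 0.860, because positions read in both libraries leave less scatter than a binomial split. The Pearson r of 0.957 moved to 0.976 (1 RPM added), 0.909 (no minimum), 0.992 (at least 100 reads), 0.938 (each position once), 0.925 (100 nt), 0.991 (10 kb) and 0.857 (single positions). Counting each position once left 3315490 records and put 50% of them in 5190 windows instead of 407, since abundant regions fill their positions. Leaving out 1 library gave 5380216 to 5787626 reads, a trimmed share of 9.23 to 9.46% and 798 to 851 candidate introns. The longest run was then 2 to 3 bins and did not pass the permutation test. Fewer reads per window are part of these settings. Requiring 8 lengths at an edge gave 834 candidate introns, and windows of at least 200 reads a longest run of 2 bins. The trimmed share inside the runs stayed 1.91 to 6.26 points above that outside in all 7 alternatives, but only in 1 of them (3.204) had the windows taken no part in choosing the runs. The odds ratio of short gaps between edges fell from 3.14 to 1.77 with depth classes pooled and reversed to 0.446 when windows as deep as the 2 deepest of the runs, which hold most short gaps there, were left out everywhere. The median candidate intron length stayed between 201 and 216 nt, inside its interval. The 30 levels of the top windows from single libraries all lay within their Poisson intervals. Depth limits windows under 10 reads, 28634 of which had none. Mismatch limits, coding or whole-gene features, per-kilobase levels, gene lists and positions along transcripts were not run, because the tables name no genes, mismatches or transcripts. No paired analysis was possible because there is only 1 group.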

Other observations

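Tests of the scatter of start positions, of edges in windows under 1000 reads, of edges at matched depth and of runs chosen in shallow windows were chosen after the results were seen; the other tests of explanations were written down before. Long stretches of the assembly had no read start. There were 546 of at least 10 kb, 12.9 Mb or 11.5% of the span, and the longest was 150.5 kb at 34738687 to 34889185, inside the first run of bins with a raised trimmed share. Windows without a read made up 36.9% of the 3400 windows in the 4 runs and 25.1% of the windows elsewhere. The 3400 windows include those of bins that the runs passed over for having too few windows of at least 50 reads. How much of the difference comes from these bins was not measured.

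In window counts the libraries differed by little more than sampling noise, with small departures in the deepest windows and at single start positions. Their trimmed shares were 0.236 points apart. Alignment lengths also differed, with 421 reads of 33 nt in replicate 1 and 169 in replicate 2. Had replicate 2 come from another strain, as its strain tag of 2138 would have it, the trimmed share per 200 kb bin was predicted to differ. The mean chi-square was 1.05 (upper limit 1.18), where at least 1.5 had been set for another strain. No pair of known strains was measured, so whether the trimmed share follows strain differences is not known. Another strain therefore stays open, above all one of nearly the same sequence. A single library sequenced in 2 runs may account for a mean chi-square of 1.013 per start position, and so may separately prepared libraries of separate cultures if they vary by under 2.32% (upper 95% limit) at single positions. The upper limit lay under the scatter that had been set for separate cultures. That setting was chosen after the result was seen and rests on no measured libraries, so it decides nothing. These explanations cannot be told apart, because no data here measure how far separately prepared libraries scatter. Whether the values measure variation between cultures is therefore open.

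The 4 runs of bins with a raised trimmed share were weighed against technical explanations. Low depth as the whole cause is argued against by windows of at least 200 reads. There the median share inside stayed 3.95 points above that outside (95% interval 2.41 to 4.87). In runs chosen from windows under 200 reads alone, a choice in which the deeper windows took no part, it was 3.204 points above (2.09 to 4.57). In the 4 runs the difference was 6.26 in windows under 200 reads and 1.91 (0.144 to 3.90) at 1000 reads or more. The intervals of these differences, here and for exon edges below, resample single windows. Windows within so few runs are not independent, so the intervals do not cover the spread between runs. Windows of at least 200 reads alone gave a longest run of only 2 bins (permutation p = 0.951). Exon edges stay open. Without reads at the edges of candidate introns called at 6 or at 5 lengths, the difference was 4.66 points (3.76 to 5.37). Only 26.0% of edges of 6 lengths belong to candidate introns of 6 lengths. At 5 lengths 9298 left and 9006 right edges stood against 1916 candidate introns, so most edges were left in. A candidate explanation, also open, is sequence that differs between these cells and the assembly. The odds ratio for a right edge followed by a left edge within 20 nt was 3.14. This test was written down before its result but after the files were seen. The odds ratio was 1.77 (0.454 to 3.07, bootstrap over windows) with 5 depth classes pooled, since short gaps are more frequent in deep windows. It was 0.446 (0.228 to 0.804) when windows as deep as the 2 deepest of the runs were left out inside and outside. By the limits written down beforehand that value goes against this explanation, but leaving out these windows was chosen after the results were seen. With edges of 3 lengths the odds ratio was 10.8 (5.98 to 18.8, 21 of 197 inside, 47 of 4296 outside) under 1000 reads. At 1000 to 3000 reads it was 1.17 (0.697 to 1.91) and above that 0.857 (0.739 to 0.996). Those depth limits were chosen after several had been tried. Apart from the bootstrap, these intervals treat edges as independent. Under 1000 reads there were too few control piles (1 inside) to test chance piles. Chance order of the bins stays open too (permutation p = 0.0419 for bins of 200 kb, from 6.3e-04 to 0.993 over the alternatives). The longest runs of the alternatives, the first where lengths tie, lay at places other than 100.2 to 101.6 Mb. No biological explanation was tested, as the design has 1 group.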
